A study of Taeniopygia guttata with 39 samples.

How the data were processed

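Total RNA of HVC, dissected from cryosections of the brains of adult female canaries, was extracted with an RNeasy Micro kit, amplified with the Ambion WT Expression Kit and labelled with the Affymetrix WT terminal labelling kit, per the labels, and hybridised to Affymetrix arrays. The 39 arrays each held 1 bird. The deposited values are log2 values processed by the authors, 1 per transcript-type identifier and array; the log2 scale was read from the values, which had no negative and no missing entries. Affymetrix Expression Console and affy are named in the labels (versions not given). The method of summarising and normalising is not given in the sources used here, and the values were used as deposited. The organism field of the labels names the zebra finch and the design text canaries; RNA of a species that differs from the array's sequences would affect levels, for all birds alike. For arrays, their number limits the precision.

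Identifiers were paired with gene symbols through unversioned RefSeq accessions in a table of the zebra finch assembly bTaeGut7.mat. Of 26061 identifiers, 2471 matched a gene, 2234 of them with an official symbol (2226 genes, 8 of them with more than 1 identifier; the brightest was used), and 23590 did not match, among them 11936 zebra finch Ensembl identifiers. All 26061 were tested, and counts refer to them; named genes come from the 2226.

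Groups were the 7 treatments of the labels. limma 3.58.1 in R 4.3.3 fitted a mean for each group to all arrays, with moderated statistics (eBayes) and Benjamini-Hochberg adjustment over the 26061 transcripts in each of 13 contrasts: each of 6 durations against control, any duration (moderated F), 5 pairs of neighbouring durations, and the mean of the 7-day and 14-day groups against the mean of the other 5. A transcript passed, or was called, at an adjusted p under 0.05, and all tests were two-sided. The contrasts, the named-gene rule, the gene lists and most alternatives were fixed before the data were examined. By that rule the text names up to 8 genes in each direction with the largest change against control (4 in other contrasts), among those that passed, had an official symbol and lay on one side of the comparison group's mean in all birds of the first group; for each list described up to 4 members; and, from a list of fixed names, ESR1, ESR2, CYP19A1, SRD5A1, BDNF, VEGFA, EGR1, DCX and PVALB where measured. Some list members are named beyond these 4, and genes that passed at all 6 durations were chosen after their values were seen. Results of 3 genes that the rule or a list would name are not reported here.

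Of 35 lists of genes fixed beforehand, 31 had at least 3 measured members and were tested at 6 durations (186 tests, adjusted together) with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Shared changes were measured as Pearson's r of log2 changes across transcripts. Beside it stand 20 simulations of unchanged groups, and values with the controls split between both comparisons. The simulations drew all arrays, controls included, independently for each transcript with its residual SD. They thus hold no variation shared by transcripts.

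The alternatives were quantile normalisation between arrays, centring each array on its median, leaving out transcripts with a mean under the 25th percentile, eBayes with trend and robust options, array weights, fits of only the groups compared, the replicate number as a block, the letter that ends the bird's number in the sample title (L, R or none, meaning not given) as a term, the mean over identifiers of a gene, an adjusted p under 0.01, a fold change of at least 1.5, and each array left out in turn. The array median as a covariate, leaving replicate 2 of the 3-hour group out of the shared fit for contrasts that do not use it, named genes as the background of camera, and the alternatives for the correlation of the 7-day and 14-day changes were chosen after seeing the data. For each contrast, 100 splits of the arrays into groups of the same sizes, the real one included, were fitted.

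The code was tested on simulated data with 200 planted changes. At 14 d, 31.3%, 89.6% and 98.5% of changes of 0.5, 1 and 2 on the log2 scale were recovered with 4 other calls among 26061 transcripts, and at 3 h 29.9%, 85.1% and all of them with 6. A planted list of 11 members was called at 14 d, and 0 of 185 other tests, by camera. These simulated arrays also drew each transcript independently and held no variation shared by transcripts. The few other calls thus test the code and give no error rate for real arrays. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.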

Results

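The series profiled HVC, a forebrain nucleus of the song control system, in adult female canaries held on short days of 9 h light and 15 h dark and described as non-breeding. The series' design text names canaries, while the organism field of the labels names the zebra finch. Birds carried a 7-mm Silastic tube under the skin, empty in 5 control birds and filled with testosterone for 1 h (6 birds), 3 h (5), 8 h (5), 3 d (6), 7 d (6) or 14 d (6). Each of the 39 arrays held RNA of a bird labelled as a biological replicate, so the number of arrays limits the precision. The labels describe the 7-day and 14-day birds as singing and all others as non-singing. The value table held 26061 entries with transcript-type identifiers, called transcripts here, with values from 0.77 to 14.09 on the log2 scale; 2226 genes could be named. Each comparison asks which transcripts differed between treated and control birds, or between durations.

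The arrays differed in overall level. Array medians ran from 7.49 to 7.91, with a mean of 7.59 ± 0.08 (SD, n = 5) in controls, 7.71 ± 0.13 (n = 6) at 1 h, 7.72 ± 0.02 (n = 5) at 3 h, 7.58 ± 0.03 (n = 5) at 8 h, 7.57 ± 0.06 (n = 6) at 3 d, 7.69 ± 0.11 (n = 6) at 7 d and 7.82 ± 0.05 (n = 6) at 14 d. The median log2 change over all transcripts against control was 0.12 at 1 h, 0.16 at 3 h and 0.00 at 8 h. It was -0.01 at 3 d, 0.10 at 7 d and 0.22 at 14 d. This shift was not common to all transcripts. At 14 d the median change was -0.004 in the brightest 1 in 5 transcripts and 0.28 in the others. At 3 h it was -0.07 in the brightest 1 in 5. Centring takes the same amount from all transcripts of an array, so it may lower bright ones too far. Counts and changes after centring share this limit. Replicate 2 of the 3-hour group had a median correlation of 0.886 with the other arrays, against at least 0.963 for each of the others. Genes named for the size of their change lay on one side of the mean of the comparison group in all birds of the other group. Of 156 gene results, 115 remained in a fit without the dimmest 25% of transcripts. Of the genes so named, FGB (2.71) and MBNL1 (2.85) in controls, FGL1 in controls (1.99), at 7 d (1.78) and at 14 d (3.26), SMU1 at 8 h (3.33) and 3 d (3.04), SLITRK6 (3.25) and CHRNA9 (3.37) at 7 d and ACAP2 at 14 d (3.37) had group means below the 5th percentile of every array (3.43 to 4.14), where the size of a change is uncertain.

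**Figure D1:**
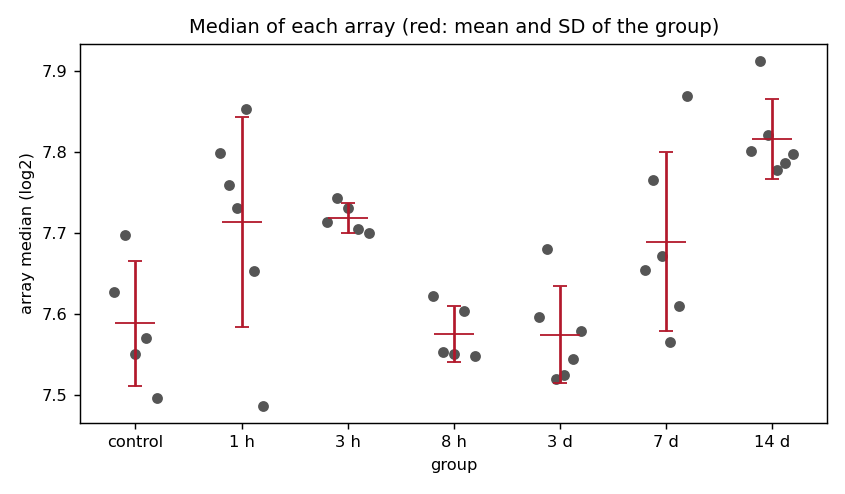
Median log2 value of each array (points) by group, with the group mean and SD in red; the vertical axis is in log2 units. The 14-day arrays lie between 7.78 and 7.91, above the 5 control arrays at 7.50 to 7.70.

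After 1 h of testosterone, the delta subunit of the GABA-A receptor, GABRD, was lower by 0.87 on the log2 scale, at 5.89 ± 0.21 (SD, n = 6) against 6.76 ± 0.33 in controls (n = 5). The serotonin receptor gene HTR2C (log2 change -0.72), the translation initiation helicase EIF4A2 (-0.81), the forkhead factor FOXO3 (-0.70) and the kinase SGK1 (-0.68) were also lower. Higher genes included FAM162B (1.67), the BRCA1 partner BARD1 (0.91) and the interferon regulatory factor IRF7 (0.67). ACAP2, JARID2 and USP33 were lower by 0.84, 0.73 and 0.68, and SNX5, ZNG1A, MRPL46 and PRPF18 were higher by 0.63 to 0.66. The synaptic vesicle gene SYT4 was lower by 0.58 and the neuropeptide Y receptor gene NPY1R by 0.55. NPY1R was lower in 5 of 6 birds. The limma fit called 2199 transcripts, 1508 higher and 691 lower, or 657 and 1282 with each array centred on its median, where MRPL46 did not pass. The count was 833, 3862, 1048, 785 and 420 without control replicates 1 to 5, 694, 974, 1462, 378 and 7531 without 1-hour replicates 1, 2, 3, 4 and 6, 5130 without the 3-hour replicate 2 and 253 in a fit of these 2 groups alone. FAM162B, IRF7, GABRD, EIF4A2, HTR2C and USP33 passed with any single array left out, 10 other named genes did not, and with the array median as a covariate (246 transcripts) FAM162B, EIF4A2 and HTR2C passed. The fit of the 2 groups alone lost 9 of 16 named genes: FAM162B, BARD1, IRF7, SNX5, ZNG1A, PRPF18, ACAP2, FOXO3 and CYP19A1.

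At 3 h, the cadherin CDH19 rose by 1.64 ± 0.26 (SE) to 9.45 ± 0.61 (SD, n = 5), the Wnt agonist RSPO1 by 1.49, DIRAS2 by 1.48 and the small heat shock protein CRYAB by 1.34. FGB (1.91), TOR1B (1.41), PIGK (1.36) and TM4SF18 (1.30) were also higher. The chaperone HSPA4 was higher by 0.71. Lower genes were CTNNB1, which encodes beta-catenin (-1.53), the growth factor receptor gene IGF1R (-1.45), NAA35 (-0.98) and RPS6KA2 (-0.97). The guanine deaminase gene GDA changed by -2.21, but by -1.23 without replicate 2, which stood at 3.45 for it; CDC123 went from -1.15 to -0.39, and did not pass without control replicate 1 (adjusted p = 0.0521). Without 3-hour replicate 2 IGF1R went to -0.96, and NAA35 and RPS6KA2 each to -0.74. TOR1B went to 1.02, PIGK to 1.09, TM4SF18 to 1.01, RSPO1 to 1.37, DIRAS2 to 1.45 and CRYAB to 1.26 without it. CDH19 (1.67), FGB (2.09) and CTNNB1 (-1.68) became larger in size without it. L3MBTL3 (-1.13) and PABPC4 (-1.01) did not pass without 3-hour replicate 2, with adjusted p of 0.152 and 0.154. FGB was 1.15 (adjusted p = 0.0672) without 3-hour replicate 1. GABRD was again lower, by 0.94. It was also lower at 7 d (-0.70) and 14 d (-0.89). At 8 h (0.15) and 3 d (-0.21) it did not pass in the limma fit, with adjusted p of 0.747 and 0.776. The durations where it passed have higher array medians than controls and bird numbers in a range apart from 8 h and 3 d, and from controls. Whether the decrease goes with treatment or with these stays open. The fit called 7459 transcripts (5162 higher, 2297 lower; 2545 and 3401 after centring), 2490 without replicate 2, and 4894, 4895 and 4061 without control replicates 3, 4 and 5. In a fit of these 2 groups alone it called 247, where 13 of 17 named genes did not pass and CDH19, RSPO1, DIRAS2 and CRYAB did, with the array median as a covariate 1886 (CTNNB1, CDC123, L3MBTL3, PABPC4 and CYP19A1 did not pass), and with the title letter as a term 4191 (without CDC123, L3MBTL3 and PABPC4).

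At 8 h, neuregulin 1 (NRG1) rose by 1.23, from 6.41 ± 0.15 (SD, n = 5) to 7.64 ± 0.13 (n = 5), and ID2, an inhibitor of basic helix-loop-helix factors, rose by 0.98. AGR3 (1.52), MYOT (1.495), HENMT1 (0.99), the sulfate transporter gene SLC26A2 (0.94) and UROC1 (0.91) were higher. EIF4A2 fell by 0.999, at 11.72 ± 0.13 against 12.72 ± 0.11 in controls (n = 5 each). The pyruvate dehydrogenase subunit gene PDHA1 (-0.91), CLIP2 (-0.95), EFHD1 (-1.12), ACTR10 (-0.94), SMU1 (-0.90), GPR78 (-0.88) and L3MBTL3 (-1.65, or -0.99 without 8-hour replicate 1) were lower. Of 3 measured proteasome subunits, PSMB2 (-0.51) and PSMB7 (-0.73) were lower (2 adjusted over the list alone). The fit called 1878 transcripts (792 higher, 1086 lower; 892 and 903 after centring), 1246 without control replicate 3, 1240 without 8-hour replicate 4 and 3282 without the 3-hour replicate 2. The count was 301 with the title letter as a term, where MYOT, SLC26A2, UROC1, L3MBTL3, EFHD1, CLIP2, PDHA1, SMU1 and GPR78 of 15 named genes did not pass, 3911 in a fit of the 2 groups alone (without L3MBTL3) and 3285 with the array median as a covariate; UROC1, EFHD1, PDHA1, SMU1 and MYOT did not pass with some single array left out, and SMU1 not after centring.

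At 3 d, few genes passed. PLEK2 was higher by 0.87, BRINP1 by 0.70 and BTBD3 by 0.62, and these were the 3 named genes that rose. EIF4A2 was lower by 0.81, at 11.90 ± 0.22 (SD, n = 6), and SMU1 by 1.20. The tyrosine kinase gene ABL1 (-0.75), ACTR10 (-0.71), ATMIN (-0.66), ARV1 (-0.56), DIPK1B (-0.55) and the endoplasmic reticulum chaperone DNAJC10 (-0.51) were lower. BRINP1, BTBD3, DIPK1B and DNAJC10 did not pass after centring, and PLEK2 and EIF4A2 alone passed with any single array left out. The fit called 273 transcripts (107 higher, 166 lower; 106 and 124 after centring), with 3029 at an unadjusted p under 0.05. The count was 117, 139 and 117 without control replicates 1, 2 and 3, 148, 131 and 139 without 3-day replicates 1, 3 and 4, 714 without the 3-hour replicate 2, 151 with the title letter as a term (without BRINP1, BTBD3, ATMIN, DIPK1B and DNAJC10) and 748 with the array median as a covariate. BRINP1, ABL1 and ACTR10 did not pass in a fit of the 2 groups alone.

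At 7 d, the first group labelled as singing, the hyaluronan synthase gene HAS2 was higher by 1.60 ± 0.30 (SE) and the corticotropin-releasing hormone binding protein CRHBP by 1.05, at 9.75 ± 0.38 (SD, n = 6) against 8.70 ± 0.31 (n = 5). The neurofilament gene NEFM was higher by 0.86, BRINP1 by 0.86, the splicing factor MBNL1 by 1.01, TM4SF18 by 0.95 and FAM162B by 1.56. CNKSR2, a scaffold of Ras signalling, was lower by 0.93, the cholesterol exporter ABCA1 by 0.90, the microtubule-associated gene MAP7 by 0.94 and FOXO3 by 0.73. ADAMTS20 (-0.92), SLITRK6 (-0.86), ACP1 (-0.84) and DHRS12 (-0.84) were lower too. The galanin receptor gene GALR1 was higher by 0.59. The fit called 2052 transcripts (1211 higher, 841 lower; 669 and 1361 after centring), 1039, 805 and 829 without control replicates 1, 4 and 5, 1175 and 843 without 7-day replicates 2 and 6, and 4209 without the 3-hour replicate 2. It called 767 with the title letter as a term, where CRHBP, MBNL1, TM4SF18, NEFM, ACP1 and EGR1 of 17 named genes did not pass, and 1298 with the array median as a covariate, where MBNL1, TM4SF18, SLITRK6, ACP1, FOXO3, CYP19A1 and EGR1 did not. MBNL1 did not pass after centring, and MBNL1, NEFM, ACP1, EGR1, SLITRK6, CYP19A1 and TM4SF18 did not pass with some single array left out.

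At 14 d, CRHBP was higher by 1.34, at 10.04 ± 0.27 (SD, n = 6), the potassium channel gene KCNK5 by 1.38, the nicotinic receptor subunit CHRNA9 by 1.30, MBNL1 by 1.45 and BEND5 by 1.45. WDTC1 (1.48), FAM162B (1.29) and FGL1 (1.27) were also higher. IGF1R was lower by 1.20, SERAC1 by 1.48, ACAP2 by 1.23, JCAD by 1.17, NUDCD1 by 1.10, TMEM63A by 1.04, PCNP by 0.97 and the calcium sensor NCALD by 0.96. Receptors for monoamines moved both ways: DRD4 (1.04), HTR2B (0.86) and HTR7 (0.69) were higher, and HTR1B (-0.52) and HTR2C (-0.53) lower. The fit called 13034 transcripts, 10182 higher and 2852 lower; after centring the split was 5297 and 5950, and WDTC1 of the 18 named genes did not pass; it also did not pass with some single array left out. With the array median as a covariate, 184 transcripts and 0 of those 18 genes passed. The covariate cannot be separated well from the group, since all 14-day medians lay above all control medians.

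**Figure D2:**
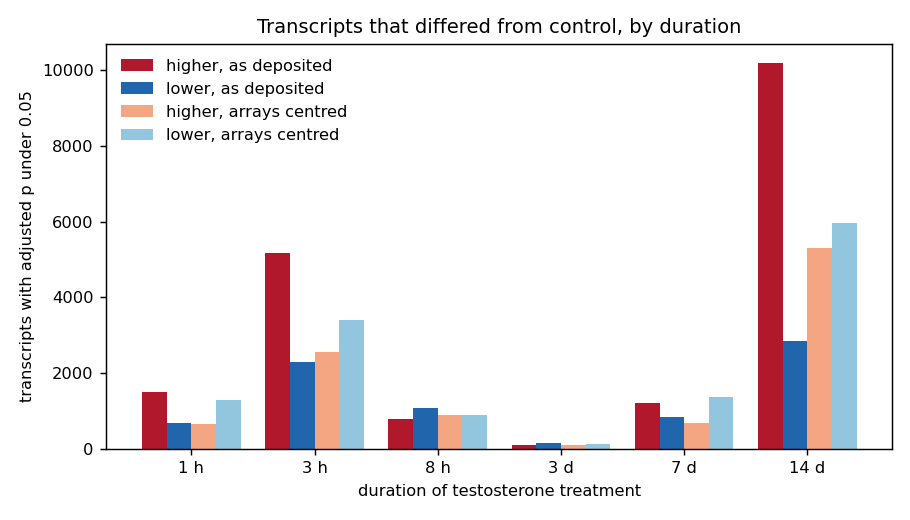
Number of transcripts with an adjusted p under 0.05 against control (vertical axis) by duration of treatment, higher and lower, for the values as deposited and with each array centred on its median. At 14 d the bars as deposited are 10182 higher and 2852 lower, and after centring 5297 and 5950.

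A test over all 6 durations called 17705 transcripts, 15632 after centring and 7761 with the array median as a covariate. EIF4A2 and HTR2C were lower, and PLEK2 higher, at each of the 6 durations; EIF4A2 changed by -0.59 at 14 d to -0.999 at 8 h, HTR2C by -0.44 at 7 d to -0.72 at 1 h, and PLEK2 by 0.49 at 14 d to 1.01 at 3 h. After centring EIF4A2 passed at each, HTR2C had an adjusted p of 0.0519 at 3 d, and PLEK2 went to 0.41 at 1 h and 0.27 at 14 d, with adjusted p of 0.116 and 0.204. Over all transcripts, 14 were higher and 34 lower at every duration (8 and 35 after centring), and all these comparisons share the 5 control arrays. The control birds' numbers also lie in a range apart from those of all treated birds. Whether changes alike at every duration go with treatment or with that range stays open. Log2 changes at 7 d and 14 d correlated at 0.686 across transcripts, which are not independent replicates. Simulated unchanged groups sharing simulated controls gave 0.547. The observed r was 0.742 without control replicate 2, and 0.629, 0.746 and 0.531 without 7-day replicates 2, 4 and 6. The covariance was 0.0787 against 0.0178 simulated, and the correlation averaged 0.525 (0.320 to 0.663) when the controls were split between the comparisons. At both durations 985 transcripts were higher and 644 lower, a number to which the shared controls add. Simulated unchanged groups had 0 called at both. Their transcripts varied independently, so this 0 was all but fixed in advance and is no baseline for real arrays. The simulated correlations have the same limit. Changes at 1 h and 14 d correlated at 0.817 and those at 8 h and 3 d at 0.742, against 0.543 and 0.524 simulated, while 8 h and 14 d gave 0.248 and 3 d and 14 d 0.201, both below the values of 0.523 and 0.544 simulated for them.

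**Figure D3:**
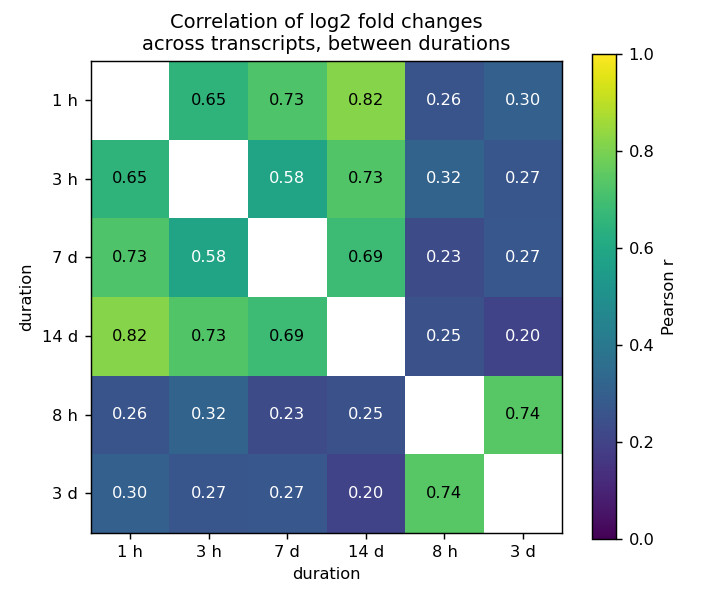
Pearson correlation across transcripts of log2 fold changes against control between pairs of durations (both axes), from 0 to 1 by colour. Pairs within 1 h, 3 h, 7 d and 14 d and the pair of 8 h and 3 d lie at 0.584 to 0.817, and all other pairs at 0.201 to 0.319. Simulated unchanged groups sharing simulated controls, with transcripts drawn independently, gave 0.501 to 0.547.

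Neighbouring durations were compared directly. The controls did not enter these differences, but they entered the variance shared by the fit. From 1 h to 3 h, CDH19 rose by 1.54, APOH by 1.48 and PEX5L by 1.42, and the metalloproteinase inhibitor TIMP3 fell by 1.08 and MBNL2 by 0.94 (-0.47 without the 3-hour replicate 2); MYOT (1.58), MORC3 (-1.11) and IGF1R (-0.98) did not pass without that replicate. From 3 h to 8 h, NRG1 rose by 1.67, CTNNB1 by 1.37 and IGF1R by 1.34 (0.85 without that replicate), while HPD fell by 2.05, the receptor activity-modifying protein RAMP3 by 1.98, the mitosis gene BIRC5 by 1.82 and TOR1B by 1.52; GDA (1.41) did not pass without it, with 0.43, and CTNNB1 not without 3-hour replicate 1 or 3. From 8 h to 3 d, the estrogen receptor gene ESR1 fell by 1.47, from 8.01 ± 0.31 (SD, n = 5) to 6.54 ± 0.69 (n = 6), with ID2 (-0.74), TOX (-0.79) and ENO2 (-0.75), and GRB10 (0.69), FH (0.50), MTPN (0.41) and PDCD4 (0.40) rose. Of these 8 genes ESR1 alone passed with any single array left out, and MTPN, PDCD4, TOX and ENO2 did not pass after centring. The counts were 1423 (805 higher, 618 lower), 8307 (2475 and 5832; 3731 and 3076 after centring) and 108 (61 and 47; 35 and 29 after centring). Without the 3-hour replicate 2 they were 663, 5230 and 316, and from 1 h to 3 h 928 passed without 1-hour replicate 5. From 8 h to 3 d the count was 171, 56, 268, 42 and 64 without 3-day replicates 1, 2, 3, 5 and 6, and 64, 57 and 45 without 8-hour replicates 1, 3 and 4. Fits of the groups compared alone called 10, 3879 and 25, and lost 6 of 8 named genes from 1 h to 3 h (MYOT, CDH19, PEX5L, MORC3, IGF1R and MBNL2), GDA, CTNNB1 and IGF1R from 3 h to 8 h and all 8 from 8 h to 3 d. The array median as a covariate gave 2496, 3581 (without GDA and CTNNB1) and 183. The title letter as a term gave 940, 652 and 29, and IGF1R from 1 h to 3 h, all named genes but NRG1 from 3 h to 8 h and GRB10, MTPN, PDCD4, TOX and ENO2 from 8 h to 3 d did not pass. IGF1R from 1 h to 3 h did not pass after centring.

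From 3 d to 7 d, across the ranges of bird numbers, ESR1 rose by 0.99, HAS2 by 1.13, CAPS2 by 1.08 and SMU1 by 1.07. NUDCD3 (-1.42), TMEM63A (-1.39), CHRNA9 (-1.29) and MYOT (-1.23) fell. From 7 d to 14 d, CHRNA9 rose by 1.62, WDTC1 by 1.62, JAZF1 by 1.55 and FGL1 by 1.49, and SERAC1 (-1.05), NUDCD1 (-0.91), NRDC (-0.84) and RBM26 (-0.82) fell. MYOT in the first comparison and WDTC1, SERAC1, NUDCD1 and RBM26 in the second did not pass with some single array left out. The counts were 4227 (2831 higher, 1396 lower; 1484 and 2328 after centring) and 3653 (3029 and 624; 1668 and 1215 after centring). Without the 3-hour replicate 2 they were 6601 and 6208. The first was 2576 without 3-day replicate 4, 2757 and 1981 without 7-day replicates 2 and 6 and 966 with the title letter as a term, where HAS2, ESR1, TMEM63A and MYOT did not pass. The second was 1204 and 2336 without 14-day replicates 2 and 3, and 1673, 1850, 844, 1222 and 7547 without 7-day replicates 1, 3, 4, 5 and 6. WDTC1 and NUDCD1 in the second did not pass with the title letter as a term. With the array median as a covariate 2441 and 122 passed, the former without TMEM63A and MYOT and the latter with JAZF1 alone of the 8 named genes.

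The groups labelled as singing (7 d and 14 d) were set against all others; song and duration go together in this contrast. CRHBP was higher by 1.05 in the singing groups, the immediate early genes FOS and EGR1 by 1.01 and 0.76, and ACTR10 by 0.66. TMEM63A (-1.04), ADAMTS20 (-0.85), CNKSR2 (-0.70) and ACP1 (-0.67) were lower. ACTR10 stood at 10.89 in the singing groups and 10.66 in controls, but at 9.72 at 8 h and 9.95 at 3 d. Low values in those groups thus enter its difference. CNKSR2 changed against control by -0.48 at 1 h and -0.83 at 3 h, groups labelled non-singing. It changed by -0.93 at 7 d and -0.935 at 14 d. EGR1 stood at 9.46 ± 0.53 (SD, n = 12) against 8.71 ± 0.29 (n = 27). The fit called 10771 transcripts (8316 higher, 2455 lower; 3542 and 4682 after centring). With the array median as a covariate it called 1479, and FOS, TMEM63A, ACP1 and CYP19A1 did not pass; with the title letter as a term it called 6794.

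Among genes of steroid action, CYP19A1, which encodes aromatase, was higher by 0.48 at 1 h, 0.47 at 3 h, 0.44 at 7 d and 0.61 at 14 d, with adjusted p of 0.0142, 0.00671, 0.0181 and 0.000287, in all treated birds of these groups; the values at 8 h and 3 d were 0.10 and 0.12 and did not pass. With the array median as a covariate CYP19A1 was 0.30, 0.29, 0.30 and 0.29 at 1 h, 3 h, 7 d and 14 d and passed at none of these durations, and in fits of the 2 groups alone it did not pass at 1 h and 3 h. After centring it passed at all 4, with 0.35, 0.34, 0.34 and 0.38. These 4 durations are those with higher array medians than controls. Their birds' numbers lie in a range apart from 8 h and 3 d, and from controls. Whether the increase goes with treatment or with these stays open. Without 1-hour replicate 4 CYP19A1 did not pass at 1 h, with 0.40, nor at 7 d without 7-day replicate 6, with 0.40, or control replicate 3, with 0.37. ESR1 did not pass at any duration against control in the main fit; its value was -0.93 at 3 d (adjusted p = 0.0512, or 0.0309 without the 3-hour replicate 2 and 0.023 with the array median as a covariate) and -0.53 at 14 d (0.0704, and 0.0222 after centring). EGR1 was higher at 7 d by 0.70 (adjusted p = 0.0327) and at 14 d by 0.99 (adjusted p = 0.000517), in 6 of 6 birds each; at 7 d EGR1 was 0.46 with adjusted p = 0.123 without replicate 6, and did not pass without 7-day replicate 5 or control replicate 1, 3, 4 or 5. EGR1 did not pass with the array median as a covariate at 7 d (0.50) or 14 d (0.54), nor at 7 d with the title letter as a term, in a fit of the 2 groups alone or after quantile normalisation. ESR2, SRD5A1, BDNF, VEGFA, DCX and PVALB were not analysed here.

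**Figure D4:**
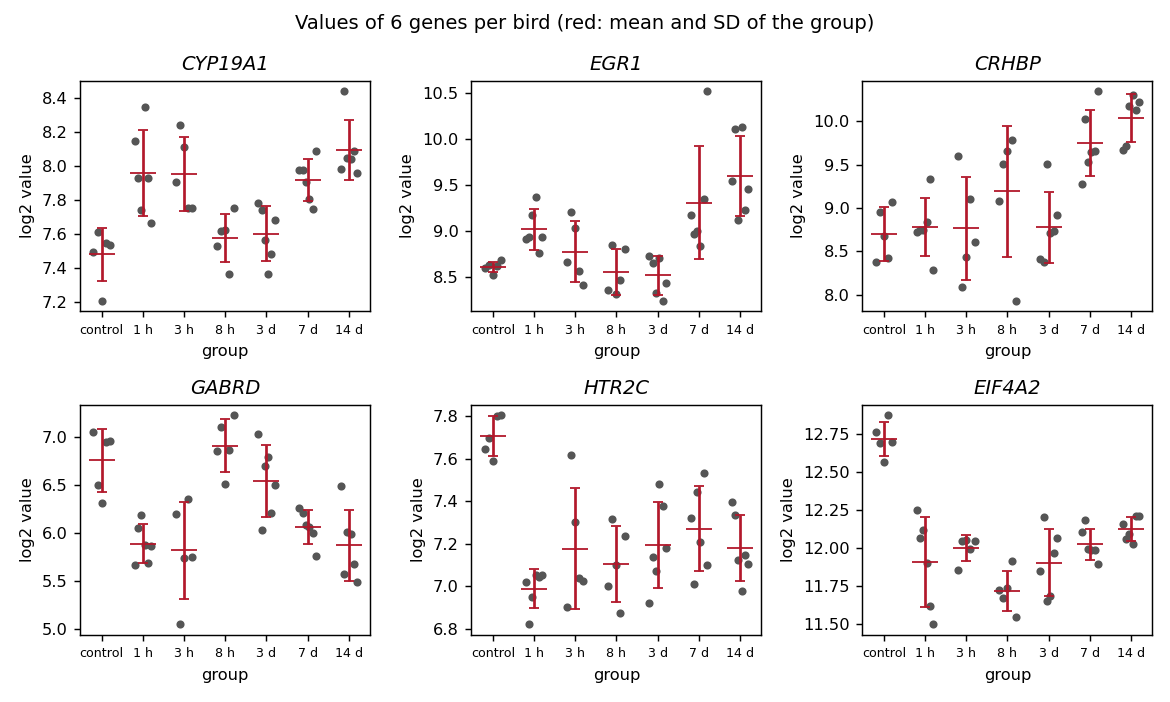
Log2 values (vertical axes) of CYP19A1, EGR1, CRHBP, GABRD, HTR2C and EIF4A2 per bird (points) by group, with the group mean and SD in red. EIF4A2 stands at 12.72 in controls, 11.72 at 8 h and 11.90 at 3 d.

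Gene lists fixed before the data were examined were tested as groups. At 14 d, 978 of all 2226 named genes were higher and 193 lower, so counts in small lists are best read against that share. At 14 d, 7 of 11 measured monoamine and acetylcholine receptors were higher and 2 lower (8 and 2 adjusted over the list alone; 5 and 2 after centring). Of 3 GABA-A and glycine receptor subunits, GABRD (-0.89) and GLRA2 (-0.38) were lower at 14 d (2 adjusted over the list alone, 2 after centring), and of 5 glutamate receptor subunits, GRM5 (-0.52) and GRIN2B (-0.36) were lower (3 adjusted over the list alone, 4 after centring). At 8 h, GRIN2B (0.49) and GRID1 (0.34) of this list were higher (GRID1 alone after centring). At 3 d none passed, with a median change of 0.19. Unadjusted camera p was 0.0489 at 3 h (toward lower), 0.03 at 8 h and 0.016 at 3 d (both toward higher), and 0.0124 at 14 d. Adjusted camera p was 0.633 at 3 h, 0.556 at 8 h and 0.402 at 3 d. At 14 d the list did not pass after adjustment either. No test compared the durations, and the bird numbers at 8 h and 3 d lie in a range apart from those at 3 h and 14 d. In steroid synthesis, SRD5A2, a steroid 5-alpha-reductase (0.76), CYP19A1 (0.61) and HSD17B2 (0.50) were higher among 5 measured genes, also 3 adjusted over the list alone and 3 after centring. Among 4 voltage-gated potassium channels KCNS1 (0.64), KCNV1 (0.51) and KCNA3 (0.38) were higher, with 3 adjusted over the list alone, and KCNA3 did not pass after centring. Endothelial and pericyte markers were higher for 3 of 3 genes, SOX18 (0.78), EMCN (0.58, in 5 of 6 birds) and TAL1 (0.35), 3 adjusted over the list alone, and for SOX18 alone after centring. By camera, 0 of the 186 tests of 31 lists and 6 durations passed, with 14 at an unadjusted p under 0.05, and 0 passed with an estimated correlation; fry, which asks whether a list's genes move one way without comparing them to others, passed 39. The smallest camera p was that of the GABA-A and glycine receptor list at 1 h (p = 0.00142, adjusted p = 0.264; adjusted p = 0.542 with an estimated correlation).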

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

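The tests of a scaling factor, of a bird of another group, of cohorts that follow the title numbers and of neighbouring durations were chosen after their result was seen; the other tests were stated before.

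Single birds stood apart from their group in 27 of 264 sets of 5 or 6 values. For independent sets chosen without regard to their values, chance gives about 1 in 20. Here most genes were chosen for large changes and the sets share arrays, so 1 in 20 is no baseline. The value given is the gap to the nearest bird as a share of the group's range. Replicate 2 of the 3-hour group had 10: SD over transcripts 0.904, median correlation within the group 0.969, MBNL2 0.904, RPS6KA2 0.753, L3MBTL3 0.722, GDA 0.805, CDC123 0.915, PABPC4 0.9, MYOT 0.809 and IGF1R 0.791. Replicate 2 of the 14-day group stood apart in array median (0.677), correlation within the group (0.778), CYP19A1 (0.722, high) and NUDCD1 (0.668). Replicate 6 of the 7-day group stood apart in correlation within the group (0.717), EGR1 (0.696, at 10.52 against 8.85 to 9.35 in the others), ACP1 (0.722) and NUDCD1 (0.675). The others were 1-hour replicate 6 for IRF7 (0.764) and IGF1R (0.672), 1-hour replicate 4 for SNX5 (0.639), control replicate 5 for SNX5 (0.847), control replicate 3 for CYP19A1 (0.714), 3-hour replicate 1 for DIRAS2 (0.786) and PEX5L (0.724), 8-hour replicate 1 for L3MBTL3 (0.731) and 14-day replicate 3 for NCALD (0.635).

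Effects of neighbouring durations differed by a direct test in 1423 transcripts from 1 h to 3 h, 8307 from 3 h to 8 h, 108 from 8 h to 3 d, 4227 from 3 d to 7 d and 3653 from 7 d to 14 d. Among 100 splits of the arrays compared, the real one included, 3, 1, 2, 1 and 3 called as many. The highest of the others called 5435, 1107, 111, 1726 and 6973. Each share was under 0.05, without adjustment over the contrasts. From 3 h to 8 h and from 3 d to 7 d, no other split reached the real count. For the comparisons with control, the real counts of 2199, 7459, 1878, 273, 2052 and 13034 at 1 h, 3 h, 8 h, 3 d, 7 d and 14 d were reached by 4, 1, 1, 1, 1 and 1 of 100 splits, with 8931, 3860, 6, 2, 6 and 1263 as the highest of the others. Over all durations (17705) and for singing groups (10771) it was 1 of 100 each, with 7379 and 9825 as the highest others. These shares were under 0.05 too. At 1 h, from 1 h to 3 h, from 8 h to 3 d and from 7 d to 14 d, other splits called more than the real one. Chance thus remains possible for these. Where the groups compared lie in different ranges of bird numbers in the sample titles, a low share cannot tell treatment from range. Some splits called several times the real count at 1 h and from 1 h to 3 h, and 6973 against 3653 from 7 d to 14 d. Arrays parted without regard to treatment can thus give counts of this size. What those splits share was not tested, and single arrays left out moved these counts as well.

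At 14 d, 10182 transcripts were higher and 2852 lower, with higher array medians (by 0.23). One scaling factor per array is argued against, since the brightest 1 in 5 transcripts had a median change of 0.00 and the others 0.28, a difference of 0.281 (SD 0.0979 over the 14-day arrays). An axis of intensity that also varies among birds of a group is a candidate explanation: across transcripts, the 14-day change correlated at 0.783 with the slope on the array median within the other treated groups (27 arrays, without replicate 2 of the 3-hour group; 0.672 with the change at 1 h, 0.546 at 3 h, 0.0474 at 8 h, -0.0415 at 3 d and 0.412 at 7 d). With the array median as a covariate, the median absolute change of the called transcripts went from 0.526 to 0.126 and the SD over transcripts from 0.421 to 0.257, while the median SE went from 0.148 to 0.162, so calls ended (184 left) through smaller fitted changes more than through larger errors. All 14-day medians lie above all control medians, so an effect of testosterone or singing on this axis stays open as untested.

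Replicate 2 of the 3-hour group correlated at 0.902 with the rest of its group, against at least 0.976 for each other array. A bird of another group in the series cannot be told apart: its highest correlation with another group's mean, 0.915, was above that with its own, and low values alone decide nothing for an array singled out by low correlations with all others. Compressed intensities could account for part: the level of a transcript explained 13.1% of the variance of its deviation (at most 5.93% in the others; slope 0.843 against 0.95 to 1.03), between the bounds set beforehand. Cells of another type in the sample cannot be told apart from other sources. The endothelial and pericyte list had a median deviation of 1.08, which met the bound set beforehand. It rests on 3 genes that went both ways (SOX18 1.09, TAL1 1.08, EMCN -1.27). For that reason the bound was not taken as met, a choice made after the values were seen. Whether such cells would raise all 3 was not tested. The other lists were at 0.205 (oligodendrocyte and myelin), 0.00 (astrocyte) and -0.248 (choroid plexus, ependyma and meninges). The microglia and immune list (2 measured genes) and the erythroid list (0) were too small to be tested. No other biological explanation was tested.

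Log2 changes correlated at 0.584 to 0.817 among 1 h, 3 h, 7 d and 14 d and between 8 h and 3 d, and at most at 0.319 across. All share the controls: simulated unchanged groups gave 0.523 to 0.547 for the former pairs, close to the 0.584 of 3 h and 7 d, and at least 0.501 for the latter. This follows the ranges of bird numbers in the sample titles, which may mark cohorts of birds or of processing: same-range pairs exceeded others by 0.442 on average, and of 15 ways to part the 6 groups in the same sizes the next highest gave 0.0116. Sharing between neighbouring durations is argued against as the source of this pattern: with the controls split between the comparisons, the lowest r of the pair farthest apart, 1 h and 14 d (0.482), was above the highest of the neighbours 3 h and 8 h (0.322, a gap of 0.16) and 3 d and 7 d (0.325). On average neighbours exceeded other pairs by 0.0968, as did 24.4% of 720 orders. Cohorts cannot be told apart from the treatments, because each duration lies in 1 range and the controls in a range of their own. A comparison across the ranges, with the controls included, thus cannot separate duration from cohort.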

How the results depend on the processing

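The array median as a covariate, the 3-hour replicate 2 left out of contrasts that do not use it, named genes as background and all alternatives for the 7-day and 14-day correlation were chosen after seeing the data. Contrasts are given as 1 h to 14 d (against control), 1-3 h, 3-8 h, 8 h-3 d, 3-7 d, 7-14 d and singing; except where the construction is named, the cause was not tested. Counts stayed within 1.5 times under quantile normalisation, eBayes with trend and robust options, the filter on dim transcripts, averaging and the replicate block (2661 at 1 h, 13000 at 14 d; 8 of 156 gene results lost), and after centring except 64 for 8 h-3 d. Replicate numbers do not pair the birds: deviations of arrays with the same number correlated at a median of 0.0318 (0.00417 for different numbers), and 4 of 39 arrays matched their own number best.

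Array weights gave 10941 at 1 h, 5202 at 8 h, 1267 at 3 d, 6902 at 7 d, 3002 for 1-3 h, 655 for 8 h-3 d, 8556 for 3-7 d, 12911 for 7-14 d and r = 0.57 for the 7-day and 14-day changes. Only the groups compared, so fewer arrays, gave 253 at 1 h, 247 at 3 h, 3911 at 8 h, 10 for 1-3 h, 3879 for 3-8 h and 25 for 8 h-3 d; it gives no separate value for any time and singing, which use all groups. The title letter gave 4191 at 3 h, 301 at 8 h, 151 at 3 d, 767 at 7 d, 940 for 1-3 h, 652 for 3-8 h, 29 for 8 h-3 d, 966 for 3-7 d and 6794 for singing; 4 of 5 birds at 8 h and 2 of 6 at 3 d, and no others, had no letter. The covariate gave 246, 1886, 3285, 748, 1298 and 184 at 1 h to 14 d, 7761 at any time, 2496, 3581, 183, 2441 and 122 for neighbouring durations in order, 1479 for singing and r = 0.635.

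By construction, stricter thresholds lowered counts: with at least 1.5-fold 463, 2418, 859, 125, 468 and 4784, then 751, 3117, 71, 972 and 1348, and 336 for singing (none for any time, an F test); with adjusted p under 0.01 245, 2007, 758, 46, 470 and 8685, then 405, 3588, 37, 1269 and 556, and 5992. fry called 39 list tests; camera called 0 in the original fit and every alternative run for the lists, with 14 at an unadjusted p under 0.05.

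With single arrays left out, counts ran from 378 to 7531 at 1 h, 2490 to 8664 at 3 h, 1240 to 3282 at 8 h, 117 to 714 at 3 d, 805 to 4209 at 7 d, 10684 to 14973 at 14 d, 16451 to 19567 at any time, 663 to 1943 for 1-3 h, 5230 to 8884 for 3-8 h, 42 to 316 for 8 h-3 d, 1981 to 6601 for 3-7 d, 844 to 7547 for 7-14 d and 7996 to 13755 for singing, r from 0.531 to 0.746, and list calls from 0 to 0. Leaving out the 3-hour replicate 2 gave the lowest at 3 h, 1-3 h and 3-8 h, the highest at any time and for singing, and the highest at 8 h, 3 d, 7 d, 14 d, 8 h-3 d and 3-7 d, which it enters through the shared variance alone.

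Of 156 gene results, the title letter lost 42, fits of the groups compared 44 of 146, the covariate 58 and centring 13. Signs changed only for values that did not pass. ESR1 at 7 d went to -0.0462 (quantile), -0.0393 (centred), -0.138 (title letter), -0.0264 and -0.0236 without control replicates 1 and 4, and -0.0284, -0.00176 and -0.0073 without 7-day replicates 2, 3 and 5 (highest 0.171 with any array left out). ESR1 for singing went to -0.0886 (quantile), -0.0832 (centred), -0.0389 (title letter), and -0.0152, -0.0141 and -0.00942 without 14-day replicate 5, 3-day replicate 2 and 7-day replicate 2 (highest 0.0904). EGR1 went to -0.0875 at 3 h (covariate) and 0.00812 at 8 h without 8-hour replicate 3 (lowest -0.124). Signal over background was not analysed here.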

Other observations

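The counts by list below use lists fixed before the data were examined, but which of them to describe was chosen after their values were seen. Counts at 14 d are best read against all 2226 named genes, of which 978 were higher and 193 lower. Splicing factors moved both ways at 14 d, with SRSF6 (1.04), MBNL1 (1.45) and PTBP2 (0.32) higher and SRSF2 (-0.77) and SF3B1 (-0.30) lower among 8 measured (3 and 2 adjusted over the list alone); PTBP2 did not pass after centring. SRSF2 was also lower at 1 h (-0.57) and 3 h (-0.75), and TRA2B at 8 h (-0.57). Of 4 genes of neurofilaments, microtubules and axon growth, GAP43, a growth cone protein, was lower at 3 h (-0.35, in 4 of 5 birds), 8 h (-0.58), 7 d (-0.40) and 14 d (-0.30), and NEFM higher at 7 d (0.86) and 14 d (0.83). Of 4 axon guidance genes the ephrins EFNA5 (0.67) and EFNB2 (0.45) were higher at 14 d (2 adjusted over the list alone). The camera p at 14 d was 0.408, 0.411 and 0.436 for these 3 lists, unadjusted.

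Among 6 growth factor genes, IGF2 was higher at 7 d (0.63) and 14 d (0.52), and GDNF at 3 h (0.46) and 14 d (0.57), while IGF1R was lower at 14 d (-1.20); 2 were higher and 1 lower adjusted over the list alone at 14 d. Of 6 glucocorticoid-responsive genes, the kinase SGK1 was lower at 1 h (-0.68) and 14 d (-0.63), NFKBIA higher at both (0.48 and 0.70), and PDK4 lower at 8 h (-0.56). Nuclear-encoded genes of oxidative phosphorylation went both ways at 14 d, with SDHA (0.66), NDUFB10 (0.62) and NDUFA9 (0.53) higher and CYCS (-0.53) and ATP5MC3 (-0.43) lower of 7 (3 and 2 adjusted over the list alone); NDUFA9 did not pass after centring. The camera p at 14 d was 0.813, 0.759 and 0.641 for these lists, unadjusted.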
